A study of Homo sapiens with 12 samples.

How the data were processed

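RNA from MCF10A cells, an established non-tumorigenic human mammary epithelial line, was measured on 12 two-colour Agilent expression arrays. Each array carried the sample labelled with Cy5 and, labelled with Cy3, a reference pooled from equal amounts of all samples, and no dye swap was among the arrays. Cells carried MYC-ER, a fusion of MYC to the hormone-binding domain of the oestrogen receptor that 4-hydroxytamoxifen (4-OHT) activates, or MYC-ER V394D, the same fusion with a substitution known to weaken binding of MYC to the zinc-finger factor MIZ1. Each population was treated with 100 nM 4-OHT or ethanol for 24 h, with 3 biological replicates in each of the 4 groups. Per the file headers, the scanner software was Agilent Feature Extraction 10.5.1.1 and the probe positions refer to the hg19 genome build.

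The spot signals and local backgrounds are intensity values in scanner units per the file headers. The processed signals in the deposited files are also intensity values, which the software had background-subtracted and dye-normalized. The scanner's ratio column is a log10 ratio of processed Cy5 to processed Cy3 per the file headers. The other deposited columns that were used are quality marks of 0 or 1 per spot. The series matrix holds log2 ratios that the authors normalized with limma, at a version the submitters' processing notes do not give. Its steps and centring stay unknown, and its column medians lay between -0.04 and 0.03. Its columns followed the Cy5 over Cy3 ratios in direction, with slopes of 1.16 to 1.89 on the ratios fitted here, so its exact scale also stays unknown. The matrix holds 26792 spots, of which 24540 have values in both populations. Across spots, 5 of its 12 columns matched another replicate number of the same group better than their own, with correlations of 0.70 to 0.97 for the best match, so replicate numbers differ between the kinds of file.

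Of 44495 array features, 1377 were controls and 43118 were spots of 34127 distinct probes. In R 4.3.3 with limma 3.58.1 and data.table (1.17.8), mean spot signals were corrected by normexp with an offset of 50 and median local backgrounds as scanned, followed by loess within each array and no scaling between arrays. Spots marked as nonuniform or population outliers were left out, spots of a probe were averaged, and a probe was kept where Cy5 was well above background on all 3 arrays of at least 1 group, with at most 3 missing values and at least 2 values per group. The brightest probe stood for each gene, other kept probes being fitted beside it with p adjusted over all probes, which gave 13721 genes, of which 11474 were well above background in Cy5 on all arrays and 50 had a missing value. Probes were named from current symbols (24618), RefSeq accessions (3360) or older symbols (499), and 5650 had no match; 12226 of the tested genes had a matched symbol. The number of arrays limits the precision, and the median standard error of a log2 fold change was 0.126.

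Groups were compared in 1 limma fit over all 12 arrays with empirical Bayes moderation, with 8 residual degrees of freedom and a Benjamini-Hochberg adjusted p under 0.05 as the threshold. The comparisons were 4-OHT over ethanol in each population, the difference between these responses, and V394D over MYC-ER cells in ethanol. Responses were also set against each other by major-axis and least-squares regression across genes. For 26 gene lists in 3 contrasts, 78 camera tests with a preset correlation of 0.01 were adjusted together; camera with an estimated correlation and fry were run beside them. These tests, the lists and the alternatives were chosen before the data were examined, except where stated. The lists were drawn from textbook knowledge of MYC, MIZ1 and SRF biology and of breast epithelial cells, not from binding data. Exploration had shown V394D fold changes and counts before the tests of technical explanations were written down.

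Named genes are those with the largest fold changes past the threshold, 6 in each direction per 4-OHT comparison and 4 for the ethanol comparison, whose 3 arrays of one group all lay above the 3 of the other. Chance gives such separation to 10% of genes. The difference of responses needed no separation. Up to 3 members of each list with the smallest p in MYC-ER cells were added, and MYC, ESR1, MAX, ZBTB17 and SRF whatever their values. Genes with uninformative clone names were left out, as were genes with probes on the Y chromosome, an exclusion made after their values were seen. A gene that met these rules is not reported here, though it stays in all tests and counts of genes and lists.

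The 12 arrays lie on 4 slides read on 2 scan days. Slide 1 holds 1 array of each group, slide 2 only MYC-ER arrays, slide 3 both V394D ethanol replicates 1 and 2 beside MYC-ER 4-OHT replicate 3, and slide 4 only V394D 4-OHT replicates 2 and 3. A slide block leaves 5 residual degrees of freedom, and values within slides 1 and 2 stand beside the results. Scanner replicate numbers did not pair the arrays: no array's deviations from its group correlated best with the array of its own number in the same population. With the numbers of the matrix 3 of 6 did. Matrix number 1 matched the slide 1 array in every group, so a pairing under the matrix numbers stays open. A replicate block was run as an alternative.

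In 1 array the fit as planned gave distorted values. V394D 4-OHT replicate 3 had local Cy5 backgrounds of up to 3927 scanner units against a median of 47. Its ratios correlated across spots at 0.35 with its own column in the authors' matrix, and at 0.96 once local backgrounds marked as outliers were replaced by the array median. The planned fit stands as the main result, and counts with replaced backgrounds are given beside each comparison; this alternative was adopted after the counts were seen. Also added after the data were examined were removal of the probe GC trend, scaling between arrays, omission of slide 4, a replicate block with the matrix numbers and slide as a random block. Other alternatives changed the background correction, normexp offset, signal column, normalization, filter, probe summary, variance model, arrays in the fit, threshold and slope genes. In all, 39 settings besides the main one were run. Most changed 1 choice, but processed signals were median centred without loess, and the matrix values were fitted in each population alone.

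The fit was tested on simulated data with 200 changed genes among 13721, with each gene's own estimated variance. In MYC-ER cells it recovered 53.7% of genes changed by 0.5 log2 units and 100% of those changed by 1, with 16 false calls among 13521 unchanged genes. For the difference of responses it recovered 7.46% at 0.5 and 87.9% at 1. A true slope of 0.5 was estimated by least squares as 0.556 and 0.509 for rising and falling genes, and by the major axis as 0.587 and 0.541. The shifted list was called, and 0 of 100 unshifted lists were called by camera. Genes were simulated independently of each other, so this cannot show false calls of lists with correlated members. In the data the estimated correlation within a list reached 0.32, for YAP/TAZ targets. All simulated arrays had the same spread per gene. Weights estimated for the real arrays, lower for noisier ones, ran from 0.353 on V394D 4-OHT replicate 3 to 3.63 on V394D ethanol replicate 2. Recovery and false calls for V394D cells and the difference of responses can therefore be worse in the data. Figures were drawn with matplotlib 3.10.9. Saturation marks and the scanner's log10 ratios were not used in the fit, and no array was left out of it.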

Results

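MCF10A mammary epithelial cells carrying MYC-ER or MYC-ER V394D were compared after 24 h in 100 nM 4-OHT or ethanol, with 3 arrays per group. MYC-ER is a MYC fusion held inactive until 4-OHT binds it, and the V394D substitution weakens the contact of MYC with MIZ1, a transcription factor through which MYC represses some genes. Fold changes are log2 values of Cy5 sample over Cy3 pooled reference from limma, given with standard errors and n = 3 arrays per group. The standard errors rest on a spread per gene pooled over all groups. They can understate the spread of V394D 4-OHT arrays, whose replicates correlated at 0.0847 to 0.351 across genes. Both ends of this range involve replicate 3, whose ratios were distorted by its local backgrounds. Median Cy5 signal above background ran from 19.3 to 113.6 scanner units on MYC-ER ethanol arrays, 39.8 to 104.8 on MYC-ER 4-OHT arrays, 13.4 to 27.4 on V394D ethanol arrays and 19.4 to 62.9 on V394D 4-OHT arrays. Cells without a MYC fusion were not among the samples, so effects of 4-OHT itself could not be separated from those of the fusion.

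The first comparison asked which transcripts changed when MYC-ER was activated. Complement receptor CR2 (chromosome 1, 207663116 to 207663175, hg19) rose by 4.22 ± 0.24, or 18.6-fold (adjusted p = 9.869e-09; 2.51 on its other probe), and the chemokine CXCL14 (chromosome 5, 134907494 to 134907553) rose by 3.10 ± 0.19 (adjusted p = 2.293e-08). For CXCL14 2 of the 3 ethanol arrays were well above background, and its rise ran from 2.14 to 5.07 across settings, so its size is uncertain. TSC22D3, a glucocorticoid-induced leucine zipper protein, rose by 2.71 ± 0.12, the Notch regulator NRARP by 2.52 ± 0.13, the matricellular protein CCN3 by 2.49 ± 0.16 and the natriuretic peptide receptor NPR3 by 2.43 ± 0.18. Among falling genes, the cytokine IL1B (chromosome 2, 113587429 to 113587488) changed by -2.49 ± 0.15 (adjusted p = 2.274e-08) and the protease urokinase, PLAU (chromosome 10, 75677050 to 75677109), by -2.19 ± 0.16 (adjusted p = 2.066e-07). Tissue factor F3 fell by 1.90, the purine-degrading enzyme XDH by 1.87, ZBED2 by 1.75 and AMOTL2, a Hippo-pathway scaffold, by 1.73, each with all 3 treated arrays below all 3 ethanol arrays. Within slides 1 and 2 the changes were 4.67 and 4.00 for CR2, 3.55 and 2.87 for CXCL14, -2.51 and -2.62 for IL1B and -2.28 and -2.12 for PLAU. In all, 1458 genes rose and 1393 fell among 13721 tested, of which 117 and 111 changed by at least 1 log2 unit. With slide as a block 2559 genes passed, and with replaced backgrounds 1723 rose and 1703 fell. None passed in limma with median centring in place of loess, where 353 had an unadjusted p under 0.05, and 128 passed with scaling between arrays.

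Growth-related lists moved up in MYC-ER cells. Of 29 genes for nucleotide, one-carbon and polyamine synthesis, 11 rose and 0 fell (median 0.31, adjusted p = 4.837e-05; adjusted p = 0.302 with an estimated correlation). They included the folate enzyme MTHFD1L (0.77 ± 0.12), the pyrimidine enzyme DHODH (0.72 ± 0.10) and the purine enzyme IMPDH1 (0.71 ± 0.11). Of 32 ribosome biogenesis genes 8 rose (median 0.26, adjusted p = 4.815e-04; adjusted p = 0.191 with an estimated correlation), among them NOLC1 at 0.88 ± 0.15, GAR1 at 0.65 ± 0.11 and NOP16 at 0.49 ± 0.12. Mitochondrial chaperones and import factors rose as a list, with 7 of 19 members up and 1 down (median 0.27, adjusted p = 0.02957; adjusted p = 0.416 with an estimated correlation). Members were TIMM44 (0.61 ± 0.18), HSPD1 (0.58 ± 0.17) and HSPE1 (0.55 ± 0.13). In the cholesterol synthesis list 6 of 21 rose (median 0.20, adjusted p = 0.006089; adjusted p = 0.416 with an estimated correlation), with INSIG1 at 1.07 ± 0.14, DHCR7 at 0.95 ± 0.11 and HMGCS1 at 0.76 ± 0.15. G1/S and DNA replication genes had 8 of 34 rising (median 0.10, adjusted p = 0.02037; adjusted p = 0.470 with an estimated correlation), led by cyclin D2, CCND2 (1.15 ± 0.14), the helicase subunit MCM6 (0.77 ± 0.13) and E2F2 (0.55 ± 0.11). Adjusted over the list alone, 11, 9, 8, 6 and 8 members rose in these lists in the order given. Their medians in the slide 1 pair of arrays were 0.29, 0.24, 0.35, 0.35 and 0.13, and in slide 2 they were 0.33, 0.29, 0.26, 0.19 and 0.07.

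Adhesion, cytoskeletal and inflammatory lists moved down in MYC-ER cells. Of 26 cell-matrix adhesion genes 16 fell and 0 rose (median -0.65, adjusted p = 6.739e-10; adjusted p = 0.0641 with an estimated correlation), including the laminin chain LAMB3 (-1.68 ± 0.13) and the hemidesmosomal integrin ITGB4 (-1.41 ± 0.10). Of 17 inflammatory cytokines 9 fell and 1 rose (median -0.76, adjusted p = 2.186e-08; adjusted p = 0.0649 with an estimated correlation), with the chemokines CXCL1 at -1.66 ± 0.13 and CCL20 at -1.62 ± 0.11 beside IL1B. Among 19 basal and squamous epithelial genes 12 fell (median -0.72, adjusted p = 1.457e-07; adjusted p = 0.0641 with an estimated correlation), with KRT6B at -1.52 ± 0.14, SPRR2A at -1.44 ± 0.14 and transglutaminase TGM1 at -1.15 ± 0.15. Targets of serum response factor fell in both lists. Of 19 immediate-early SRF-TCF genes 14 fell and 1 rose (median -0.61, adjusted p = 2.186e-08). Of 32 cytoskeletal SRF-MRTF genes 16 fell and 0 rose (median -0.45, adjusted p = 1.365e-07). With an estimated correlation these gave adjusted p = 0.165 and adjusted p = 0.181. Examples were the phosphatase DUSP6 (-1.15 ± 0.13), JUN (-1.11 ± 0.11), KLF6 (-1.09 ± 0.12), the actin-binding LIMA1 (-1.15 ± 0.15), tropomyosin TPM4 (-1.06 ± 0.12) and myosin light chain MYL6 (-0.78 ± 0.10). Of 18 YAP/TAZ targets 11 fell (median -0.44, adjusted p = 3.267e-07; adjusted p = 0.224 with an estimated correlation), with the kinase NUAK2 at -1.09 ± 0.11 beside F3 and AMOTL2.

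Lysosomal, luminal and MIZ1-related lists fell by smaller amounts. Of 29 lysosome and autophagy genes 7 fell and 1 rose (median -0.21, adjusted p = 0.01472; adjusted p = 0.504 with an estimated correlation). Those that fell included cathepsin CTSB (-0.82 ± 0.13) and LAMP2 (-0.59 ± 0.12; -0.36 and -0.18 on other probes, which did not pass). Among 15 luminal epithelial genes 6 fell and 2 rose (median -0.33, adjusted p = 0.02863; adjusted p = 0.387 with an estimated correlation): claudin CLDN4 changed by -1.43 ± 0.18 and mucin MUC1 by -0.76 ± 0.16, whereas EPCAM rose by 0.95 ± 0.12. Of 19 genes listed from textbook knowledge as bound and repressed by MYC and MIZ1, 5 fell and 2 rose (median -0.23, adjusted p = 0.04022, and adjusted p = 0.203 with an estimated correlation). Binding to these genes was not measured here. Members were the integrins ITGA6 at -1.02 ± 0.15 and ITGA1 at -0.82 ± 0.12 and the stress gene GADD45B at -0.79 ± 0.13. ITGA1 was well above background on 2 of the 3 treated arrays. This list was not called in V394D cells (median -0.08, 1 of 19 lower, adjusted p = 0.198) or for the difference of responses (median -0.21, adjusted p = 0.184; 0.0251 by fry), and its call in MYC-ER cells was kept under 22 of 34 settings. Adjusted over the list alone, 19 adhesion, 12 inflammatory, 13 basal, 14 SRF-TCF, 18 SRF-MRTF, 11 YAP/TAZ, 13 lysosomal, 7 luminal and 5 MIZ1-list genes fell. Within slides 1 and 2 the adhesion medians were -0.62 and -0.73, the inflammatory medians -0.88 and -0.80 and the SRF-MRTF medians -0.45 and -0.49.

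**Figure D1:**
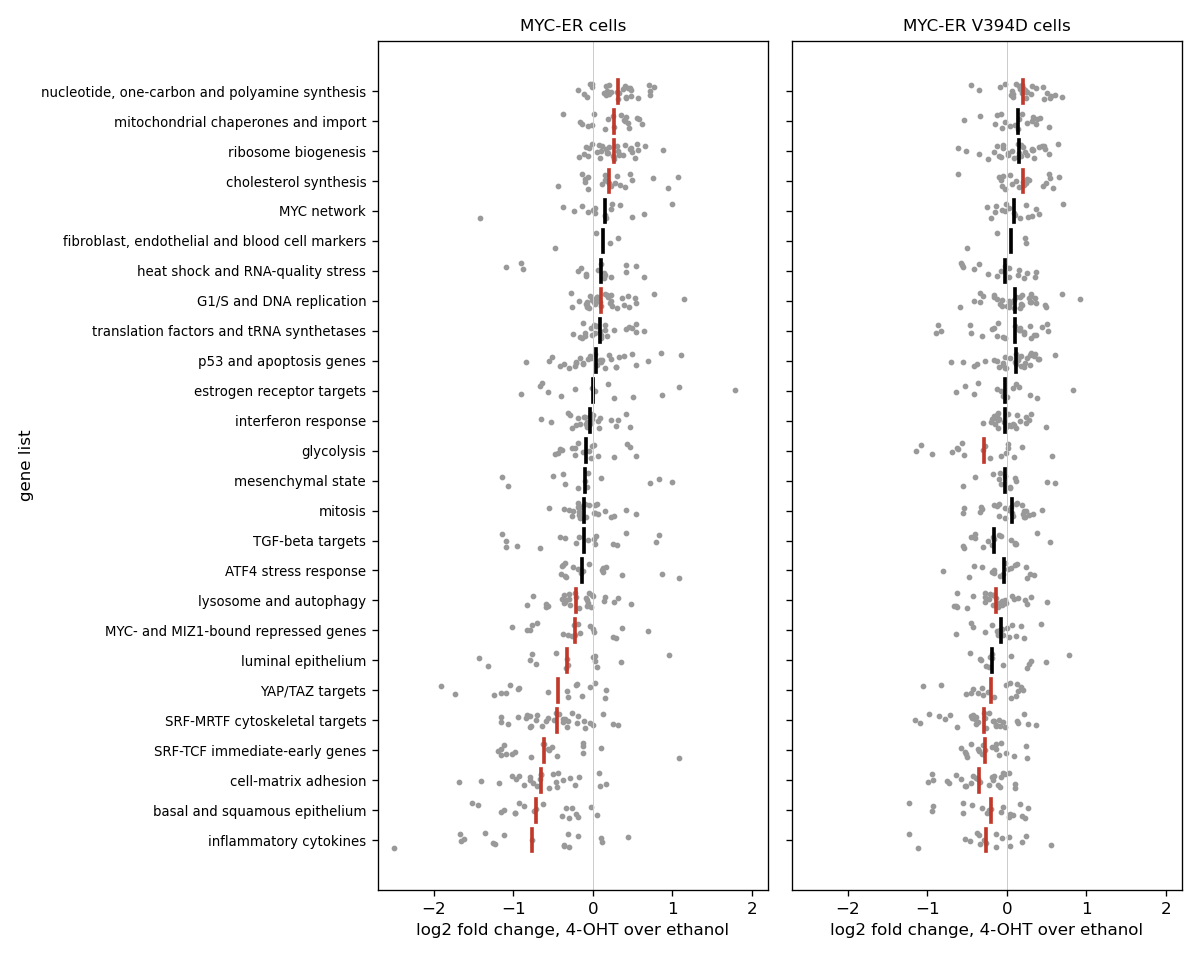
Log2 fold changes of 4-OHT over ethanol (x axis) for the members of each gene list (y axis) in MYC-ER and MYC-ER V394D cells; points are genes, bars are list medians, and red bars mark lists past the camera threshold with the preset correlation. In MYC-ER cells the inflammatory list had a median of -0.76 and the nucleotide list a median of 0.31.

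MYC transcripts themselves fell in MYC-ER cells, by -1.42 ± 0.15 (chromosome 8, 128753268 to 128753327; adjusted p = 5.744e-06), with all 3 treated arrays below all 3 ethanol arrays. The files do not say whether this probe reads the endogenous gene, the transgene or both. In V394D cells MYC changed by -0.20 ± 0.15, which did not pass (adjusted p = 0.423). Its log2 ratios on V394D 4-OHT replicates 1 and 2 were -0.344 and -0.300, below all V394D ethanol arrays. On replicate 3, the array with distorted values, the ratio was 0.241. In the slide 1 pair MYC changed by -0.45. Its partner MAX (0.23 ± 0.16), the MIZ1 gene ZBTB17 (-0.13 ± 0.14), ESR1 (0.03 ± 0.16) and SRF (0.31 ± 0.15) did not pass in MYC-ER cells, nor did they in V394D cells, with changes of 0.37 ± 0.16, -0.14 ± 0.14, 0.03 ± 0.16 and -0.14 ± 0.15.

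**Figure D2:**
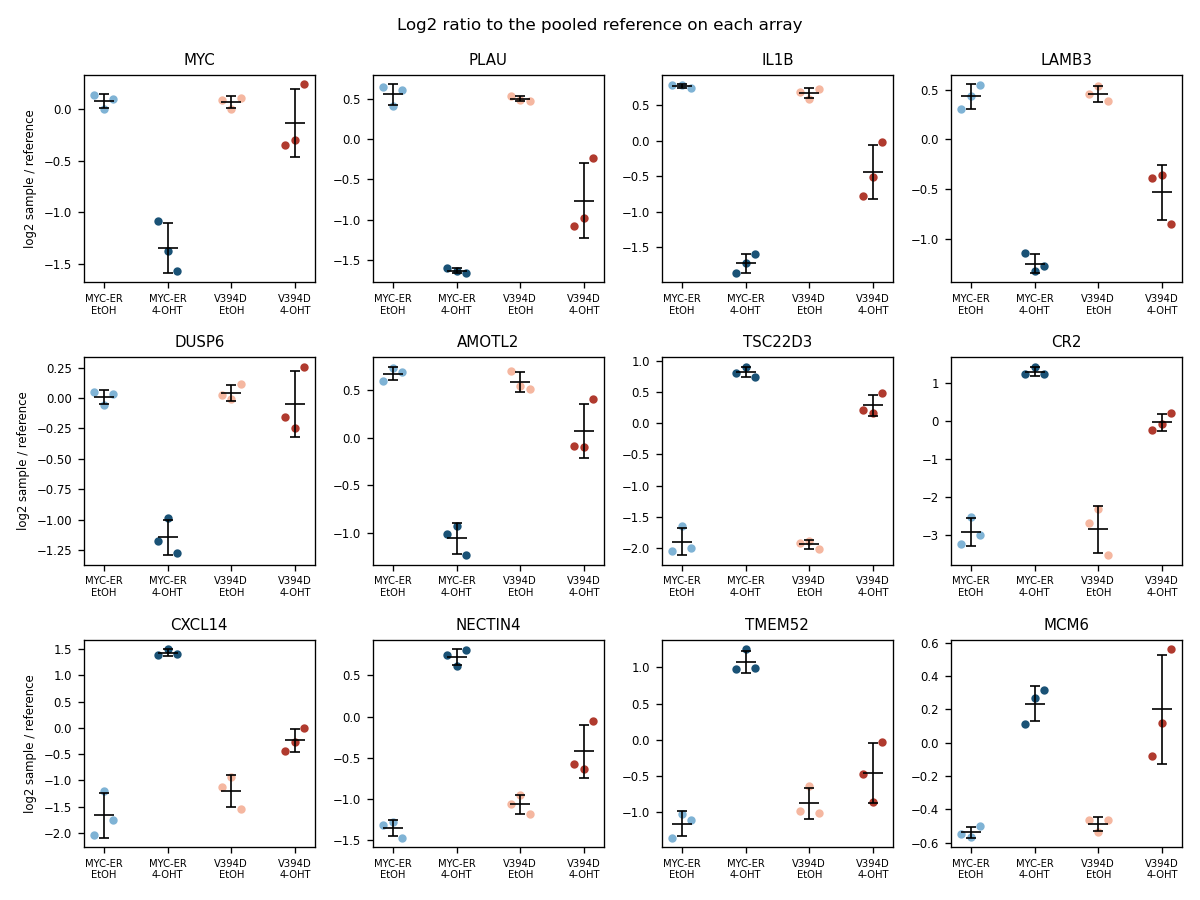
Log2 ratio of sample to pooled reference (y axis) on each array for 12 named genes, by group (x axis); points are arrays, horizontal lines are means and error bars are SD of 3 arrays. For MYC the fold change was -1.42 in MYC-ER cells and -0.20 in V394D cells, where V394D 4-OHT replicate 3 lay at 0.241 and the other treated arrays below ethanol.

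The next comparison asked what 4-OHT did in cells with MYC-ER V394D. CR2 rose by 2.81 ± 0.24 (adjusted p = 6.033e-06), with 1 of the 3 ethanol arrays well above background, but by 0.86 on its other probe (adjusted p = 0.0483). TSC22D3 rose by 2.23 ± 0.12 (adjusted p = 5.786e-08), the G-protein regulator RGS16 by 1.78 ± 0.13, the fatty-acid transport proteins SLC27A5 and SLC27A2 by 1.70 ± 0.14 and 1.31 ± 0.13, and the transcription factor BATF3 by 1.29 ± 0.11. PLAU fell by 1.27 (SE 0.17, adjusted p = 4.903e-04) and IL1B by 1.11 (SE 0.15, adjusted p = 6.340e-04), and all 3 treated arrays lay below all 3 ethanol arrays for both. The keratins KRT6C (-1.45 ± 0.31) and KRT14 (-1.23 ± 0.29), the cytokine CSF3 (-1.23 ± 0.27) and filamin FLNA (-1.15 ± 0.27) also fell, with SDs of 0.98, 0.92, 0.79 and 0.83 across the treated arrays. In the slide 1 pair, the only V394D pair on 1 slide, they changed by -0.30, -0.26, -1.11 and -0.59, so most of the fall of both keratins rested on the other arrays, while CR2 changed by 3.30, TSC22D3 by 2.23, PLAU by -1.56 and IL1B by -1.52. Other probes of CSF3 (-0.74, adjusted p = 0.0562) and FLNA (-0.26, adjusted p = 0.268) did not pass. The V394D 4-OHT arrays were unlike each other. Across genes V394D 4-OHT replicate 2 correlated at 0.556 to 0.721 with the 6 MYC-ER arrays, but at 0.240 and 0.351 with replicates 1 and 3 of its group. Replicates 1 and 3 correlated at 0.0847 with each other. The values that involve replicate 3 rest on its distorted ratios. Across spots its ratios correlated at 0.304 with its own ratios after backgrounds were replaced, against 0.986 or more on the other arrays. How far replaced backgrounds change the correlations between replicates was not tested. The reason for the low correlation of replicates 1 and 2 was not tested either. In all, 481 genes rose and 328 fell, of which 19 and 24 changed by at least 1 log2 unit. With replaced backgrounds 852 rose and 1356 fell, with slide as a block 13 passed, without slide 4 87 passed, without V394D 4-OHT replicate 2 496 passed, and without V394D ethanol replicate 3 143 passed. None passed in limma with median centring, where 2823 had an unadjusted p under 0.05, and 1 passed with scaling between arrays.

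Of the 26 lists, 10 were called in V394D cells. Nucleotide, one-carbon and polyamine genes rose as a list, 5 of 29 members passing (median 0.21, adjusted p = 8.730e-04; adjusted p = 0.387 with an estimated correlation), with DHODH at 0.60 ± 0.10 and MTHFD1L at 0.46 ± 0.12 (0.58 and 0.28 on other probes, the last not passing). Cholesterol synthesis had 6 of 21 rising (median 0.20, adjusted p = 0.01210; adjusted p = 0.447 with an estimated correlation), including INSIG1 (0.65 ± 0.14) and DHCR7 (0.58 ± 0.11). Cell-matrix adhesion fell, 7 of 26 members passing (median -0.35, adjusted p = 2.186e-08; adjusted p = 0.0641 with an estimated correlation), with LAMB3 at -0.99 ± 0.13 and ITGB4 at -0.75 ± 0.10. SRF-MRTF genes fell, 7 of 32 passing (median -0.28, adjusted p = 7.175e-07; adjusted p = 0.191 with an estimated correlation), and SRF-TCF genes fell, 3 of 19 passing (median -0.27, adjusted p = 3.675e-04; adjusted p = 0.295 with an estimated correlation). Glycolysis genes fell in V394D cells, 4 of 18 lower and 1, hexokinase HK2 at 0.56 ± 0.12, higher (median -0.29, adjusted p = 8.909e-04; adjusted p = 0.224 with an estimated correlation). In MYC-ER cells that list had a median of -0.08 and adjusted p = 0.789. Inflammatory cytokines fell, 4 of 17 passing (median -0.26, adjusted p = 0.001471), as did YAP/TAZ targets, 4 of 18 (median -0.20, adjusted p = 0.005000). Basal genes fell, 4 of 19 (median -0.19, adjusted p = 0.009665), and lysosomal genes, 1 of 29 (median -0.14, adjusted p = 0.009665). With an estimated correlation these 4 lists gave adjusted p = 0.224, adjusted p = 0.447, adjusted p = 0.224 and adjusted p = 0.470.

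Adjusted over the list alone, 6 nucleotide and 6 cholesterol genes rose, and 12 adhesion, 11 SRF-MRTF, 4 SRF-TCF, 9 glycolysis, 6 inflammatory, 4 YAP/TAZ, 6 basal and 5 lysosomal genes fell in V394D cells. In the slide 1 pair, the adhesion median was -0.28, the SRF-MRTF median -0.34, the inflammatory median -0.29, the glycolysis median -0.13 and the nucleotide median 0.16. Slides 2, 3 and 4 held no V394D pair of ethanol and 4-OHT arrays. Median centring turned the V394D medians of the adhesion, glycolysis, lysosomal, basal, SRF-MRTF and SRF-TCF lists, and none of these passed there.

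The responses shared many genes. Among genes rising in MYC-ER cells 390 also rose in V394D cells, where independence gives 51.1, and among falling genes 224 also fell, where independence gives 33.3. No gene was called in opposite directions. V394D fold changes had the MYC-ER sign for 96.0% of rising and 84.8% of falling MYC-ER genes. The median rise was 0.52 in MYC-ER and 0.30 in V394D cells, and the median fall was -0.55 and -0.20. Choosing genes by their MYC-ER values can enlarge the MYC-ER medians. For genes chosen without 1 MYC-ER replicate, the left-out replicate had median rises of 0.48 to 0.70, against 0.65 to 0.70 in the choosing replicates. V394D cells had 0.33 to 0.36. For falling genes the left-out replicate had medians of -0.51 to -0.63 and V394D cells -0.20 to -0.27.

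The difference of responses was tested directly to ask which genes responded unequally in the populations. TMEM52, well above background on 1 of the 3 V394D ethanol arrays, rose more in MYC-ER than in V394D cells by 1.82 ± 0.25, NRARP by 1.44 ± 0.18, the adhesion molecule NECTIN4 by 1.44 ± 0.20, the adaptor SH2B2 by 1.41 ± 0.17 and CCN3 by 1.39 ± 0.23. CXCL14 also passed, but in V394D cells, where no ethanol array was well above background, its rise is known only to be at least 1.76-fold, so the size of its difference is not known. IL1B fell more in MYC-ER cells, with a difference of -1.38 ± 0.21 (adjusted p = 0.005996), as did the cornified-envelope protein gene SCEL (-1.37 ± 0.20; 2 of 3 MYC-ER 4-OHT arrays well above background), FGFBP1 (-1.28 ± 0.21), CLDN4 (-1.25 ± 0.25), MYC (-1.22 ± 0.21) and AMOTL2 (-1.21 ± 0.19). CR2 (1.41 ± 0.33, adjusted p = 0.0593), PLAU (-0.93 ± 0.23, adjusted p = 0.0828) and TSC22D3 (0.49 ± 0.18, adjusted p = 0.265) did not pass this test. Of 133 genes that passed, 43 had the higher and 90 the lower value in MYC-ER cells, and all were called in MYC-ER cells in that same direction. Other probes of CXCL1 (-0.66), NPR3 (0.70), PMEPA1 (-0.37) and SPRR2A (-0.59) did not pass, and another probe of CR2 did (1.66, adjusted p = 0.0318). On slide 1 alone the difference was -0.99 for IL1B, -1.67 for SCEL, -0.94 for FGFBP1, -1.24 for CLDN4, -1.06 for MYC and -0.91 for AMOTL2. V394D 4-OHT replicate 3, the array with distorted values, had the highest of the V394D 4-OHT ratios for these genes except CLDN4. For IL1B it had -0.025, against -0.786 and -0.513 on replicates 1 and 2. Such ratios enlarge those differences. With replaced backgrounds 228 genes passed, with slide as a block 1, without V394D ethanol replicate 2 27, and without V394D 4-OHT replicate 1 340. None passed in limma with median centring or scaling, where 82 and 598 had an unadjusted p under 0.05.

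**Figure D3:**
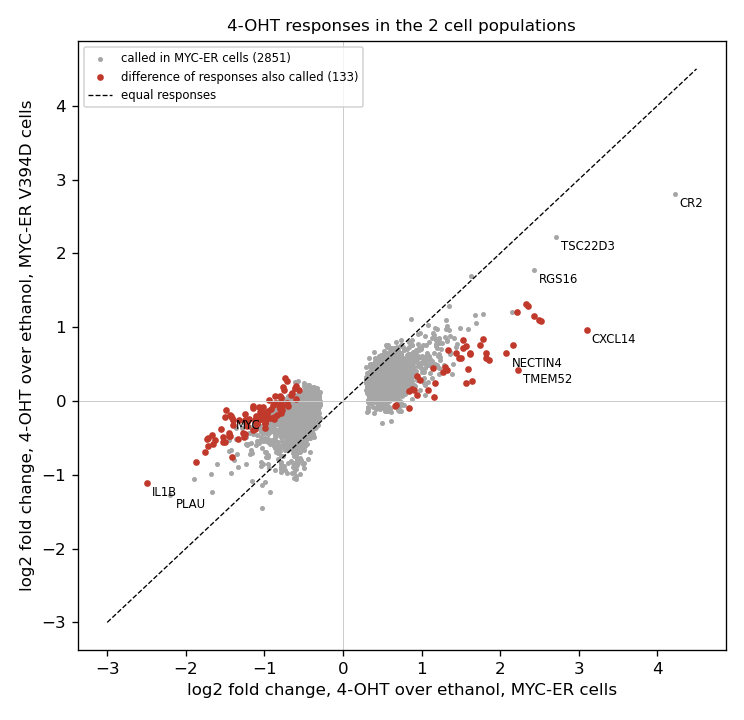
Log2 fold change of 4-OHT over ethanol in MYC-ER V394D cells (y axis) against MYC-ER cells (x axis) for the 2851 genes called in MYC-ER cells; red points mark the 133 genes whose difference of responses also passed, and the dashed line marks equal responses. TMEM52 lay at 2.23 in MYC-ER and 0.42 in V394D cells.

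Of the 26 lists, 9 differed between the responses. Inflammatory cytokines had the lowest p (median difference -0.47, adjusted p = 9.495e-09; adjusted p = 0.0649 with an estimated correlation), 5 of 17 members passing, with CXCL1 at -1.19 ± 0.19 and CCL20 at -1.09 ± 0.16. YAP/TAZ targets (median -0.33, adjusted p = 1.171e-06; adjusted p = 0.243 with an estimated correlation) had 1 member passing and SRF-TCF genes (median -0.43, adjusted p = 3.239e-06; adjusted p = 0.203 with an estimated correlation) had 3, DUSP6 at -1.06 ± 0.18, JUN at -0.82 ± 0.16 and KLF6 at -0.78 ± 0.17. Basal genes (median -0.52, adjusted p = 1.485e-05; adjusted p = 0.0716 with an estimated correlation) included TGM1 at -1.07 ± 0.21, SPRR2A at -1.01 ± 0.20 and KRT6B at -0.97 ± 0.19. Adhesion genes differed by a median of -0.25 (adjusted p = 3.550e-04; adjusted p = 0.181 with an estimated correlation), with ITGB4 passing at -0.65 ± 0.15. Luminal genes differed by -0.27 (adjusted p = 0.006098; adjusted p = 0.295 with an estimated correlation) and SRF-MRTF genes by -0.20 (adjusted p = 0.02079; adjusted p = 0.447 with an estimated correlation). Without the SRF-MRTF genes shared with other lists, 29 members gave adjusted p = 0.0540. Ribosome biogenesis (median 0.15, adjusted p = 0.02037; adjusted p = 0.328 with an estimated correlation) and glycolysis (median 0.27, adjusted p = 0.005000; adjusted p = 0.295 with an estimated correlation) differed upwards, and no single member of either passed.

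Adjusted over the list alone, 9 inflammatory, 7 YAP/TAZ, 10 SRF-TCF, 6 basal, 10 adhesion, 4 luminal and 4 SRF-MRTF genes had lower differences. On slide 1 the median differences were -0.60 for inflammatory, -0.36 for YAP/TAZ, -0.41 for SRF-TCF, -0.63 for basal, -0.34 for adhesion, -0.24 for luminal, -0.18 for SRF-MRTF, 0.10 for ribosome biogenesis and -0.01 for glycolysis genes. With slide as a block the glycolysis median was -0.02 and its call was lost.

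Across genes, the size of V394D responses was set against MYC-ER responses, and genes are not independent replicates. Over the 1458 rising genes, the least-squares slope was 0.478 (SD 0.0209 over single V394D 4-OHT arrays), the major-axis slope 0.636 (SD 0.155) and Pearson r 0.643. For the 1393 falling genes the least-squares slope was 0.452 (SD 0.0766), the major-axis slope 0.928 (SD 0.752) and r 0.468, so the kinds of slope disagreed there. SLC27A5 lay near equality, at 1.63 ± 0.14 in MYC-ER and 1.70 ± 0.14 in V394D cells, and TMEM52 far from it, at 2.23 ± 0.17 and 0.42 ± 0.17. Without V394D 4-OHT replicate 1 the major-axis slope of falling genes was 1.80, and with the authors' matrix values it was 1.91.

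The last comparison set ethanol-treated V394D cells against ethanol-treated MYC-ER cells. The splicing gene SNRNP70 (1.55), the keratin pseudogene KRT42P (1.48), the basal keratin KRT14 (1.46) and the proteoglycan SDC4 (1.41) were higher in V394D cells, each with adjusted p = 0.04754 and all 3 arrays above the 3 MYC-ER arrays. The histone genes H1-1 (-1.03) and H4C5 (-0.81), the pseudogene SLC9A7P1 (-0.67) and the mitochondrial factor TFAM (-0.66; -0.38 on another probe, which did not pass) were lower. In all, 184 genes were higher and 44 lower, and the lowest adjusted p was 0.04754. The log2 ratios correlated with probe GC content at 0.06, 0.24 and 0.36 on the V394D ethanol arrays. On the MYC-ER ethanol arrays these correlations were -0.12, -0.08 and -0.21. Median Cy5 signals above background were 13.4 to 27.4 and 19.3 to 113.6 scanner units in these groups. How far either difference enters the named genes was not tested. With replaced backgrounds none passed in limma, where 3215 had an unadjusted p under 0.05, and with slide as a block 7 passed. None passed in limma when any 1 array was left out, with 1869 to 3143 at an unadjusted p under 0.05, except that 720 and 1201 passed without V394D 4-OHT replicates 1 and 2.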

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

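Tests chosen after results were seen were the use of both kinds of slope for bright genes, the ratio form of the slide 1 test and the repeats with replaced backgrounds, and V394D fold changes had been explored before any of the tests of technical explanations.

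A difference between the populations in their 4-OHT response was the reason to list the results in this part. It passed the test for 133 genes. Among named genes that rose more in MYC-ER cells, the difference of log2 fold changes was 2.14 for CXCL14, 1.82 for TMEM52, 1.44 for NRARP, 1.44 for NECTIN4, 1.41 for SH2B2, 1.39 for CCN3, 1.28 for NPR3, 1.06 for BATF3, 1.02 for SLC27A2, 0.95 for MYB and 0.93 for GREB1. The values for CXCL14 and GREB1 are not exact, because no V394D ethanol array was well above background for either. The V394D rise of CXCL14 is known only to be at least 1.76-fold, and for GREB1 no size is given. TMEM52 and NPR3 were well above background on 1 of the 3 V394D ethanol arrays. Among those that fell more, it was -1.38 for IL1B, -1.37 for SCEL, -1.28 for FGFBP1, -1.25 for CLDN4, -1.22 for MYC, -1.21 for AMOTL2, -1.19 for CXCL1, -1.09 for CCL20, -1.07 for TGM1, -1.06 for ZBED2, -1.06 for DUSP6 and -1.04 for XDH. Smaller differences were -1.01 for SPRR2A, -0.97 for KRT6B, -0.82 for JUN, -0.80 for PMEPA1, -0.78 for KLF6, -0.75 for SNAI2 and -0.65 for ITGB4. All of these differences include V394D 4-OHT replicate 3, the array with distorted values. CXCL1, NPR3, PMEPA1 and SPRR2A each had another probe that did not pass. The lists that differed had median differences of 0.15 for ribosome biogenesis, 0.27 for glycolysis, -0.20 for SRF-MRTF, -0.43 for SRF-TCF, -0.33 for YAP/TAZ, -0.25 for adhesion, -0.47 for inflammatory, -0.52 for basal and -0.27 for luminal genes. None of these list differences passed with an estimated correlation, where the lowest adjusted p was 0.0649.

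V394D responses were smaller than MYC-ER responses over genes called in MYC-ER cells, by medians and least-squares slopes. Major-axis slopes were 0.636 (SD 0.155) for rising and 0.928 (SD 0.752) for falling genes, and were steeper with the authors' matrix values. Choice of genes by their MYC-ER responses as the whole cause is argued against: the left-out MYC-ER replicate had mean least-squares slopes of 1.03 (SD 0.105) and 0.992 (SD 0.0576) over rising and falling genes, against 0.499 and 0.448 for V394D cells. Slide differences as the whole cause are argued against by slide 1 alone. There the ratio of V394D to MYC-ER least-squares slopes over rising genes was 0.531, or 0.521 with replaced backgrounds. The V394D slopes themselves were 0.64 and 0.60. Medians as scanned were 0.34 in V394D and 0.70 in MYC-ER cells. Compression by weaker Cy5 signal, which 4 of the 6 V394D arrays but also 1 MYC-ER array had at under 30 scanner units, stays open. Over 213 rising genes with bright spots the least-squares slope was 0.574 while the major-axis slope was 1.21. Over 348 falling genes with bright spots they were 0.374 and 1.56. The bound set beforehand of under 0.75 named no kind of slope. A lower activity of the V394D protein may also contribute and was not tested, since the amount of either fusion protein was not measured.

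Genes called lower in V394D cells had probes of high GC content, with a median of 51.7% against 43.3% over all tested genes. Genes called higher in V394D cells had a median of 40%. In MYC-ER cells it was 41.7% for rising and 45% for falling genes. The 90 genes with lower differences of responses had 38.3%, and the 43 with higher differences had 45%. The tests that follow cover only the genes called lower in V394D cells. After the GC trend of each array was removed, 320 genes were lower in place of 328, above the bound of 75 percent set beforehand. With replaced backgrounds 906 were lower in place of 1356, a count of 66.8%, which lies between both bounds. These are counts from separate fits and do not say how many genes were shared. Of 130 genes called lower without slide 1, 95.4% were lower in the slide 1 pair, but with replaced backgrounds the share was 83.3% of 2213, again between the bounds. The bounds met in the planned fit are not read as excluding either explanation, because that fit correlated at 0.35 with the authors' values on V394D 4-OHT replicate 3 and the better-matching backgrounds gave other answers. A GC-linked bias and an effect of slide 4 could therefore each account for part of these calls, and a biological change of GC-rich transcripts was not tested.

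Other splits of the arrays were counted for each comparison. For MYC-ER cells, V394D cells and the ethanol comparison, 10 splits are too few for a share under 0.05; the real splits gave 2851, 809 and 228 genes, and in each case 1 split, the real one, gave as many, the highest other giving 0. For the difference of responses, 9 of 100 drawn splits gave at least the real 133 genes, the highest other giving 3750. The 8 other splits all kept the MYC-ER treatment groups and regrouped V394D arrays, so the MYC-ER response itself stayed in the contrast. The split with 3750 had the V394D treatment labels exchanged, which adds the V394D response to the MYC-ER response. This count therefore cannot decide on chance, which is not excluded.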

How the results depend on the processing

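Alternatives chosen after the data were examined were replaced local backgrounds, removal of the GC trend, scaling between arrays, slide as a random block, omission of slide 4 and a replicate block with the matrix numbers; the cause of the changes given here was not tested unless stated. Of named-gene calls, 81 of 97 in MYC-ER cells, 11 of 50 in V394D cells and 7 of 30 differences of responses kept direction and threshold under at least 90% of settings, and 0 kept them under all, since no gene passed with median centring. Of list calls, 9 of 14, 5 of 10 and 6 of 9 did so. The all-gene median, -0.0039, 0.0345, -0.0218 and -0.0365 in the MYC-ER, V394D, difference and ethanol comparisons as planned, was 0.21, 1.09, -0.83 and -0.80 with median centring, and 0.19 and -0.20 in the V394D and difference comparisons with scaling; gene and list values under such settings are given with that median subtracted. Processed signals, which were median centred without loess so that signal and normalization changed together, put it at 0.14, 0.25, -0.09 and -0.25, and then gave 2272 higher and 722 lower in MYC-ER, 3616 and 587 in V394D and 9 and 233 in the ethanol comparison. Signal over background limits V394D ethanol arrays most, where median Cy5 net signals were 13.4 to 27.4.

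Genes changed in MYC-ER cells (2851) were 0 with median centring, 128 with scaling, 1477 at an adjusted p under 0.01 and 228 with a log2 change of at least 1, these last by construction. Genes changed in V394D cells (809) were 2430 without background correction, 4203 with median-centred processed signals, 0 with median centring, 448 without the filter, 13 with slide as a fixed block, 193 with only the 6 arrays compared, 2208 with replaced backgrounds, 1 with scaling, 87 without slide 4, 161 at 0.01 and 43 at a change of 1. The difference of responses (133) was 247 without background correction, 78 with offset 16, 36 with median-centred processed signals, 0 with median centring, 83 without the filter, 84 with a replicate block, 1 with slide as a fixed block, 228 with replaced backgrounds, 0 with scaling, 30 without slide 4, 25 at 0.01 and 41 at a change of 1. With a replicate block MYC-ER, V394D and ethanol counts were 2513, 589 and 235.

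The ethanol comparison (228) gave 0 without background correction, with offset 16, with median centring, without the filter, with the mean of a gene's probes, with an intensity trend, with slide as a random block, with replaced backgrounds, with scaling and at 0.01, where limma gave 132 (median centring) to 3633 (no filter) at an unadjusted p under 0.05. It gave 7 with slide as a fixed block, 2265 with only the 6 arrays, 3970 with array weights, 353 with the GC trend removed, 590 with a replicate block by matrix numbers, 1470 without slide 4 and 55 at a change of 1.

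Leaving out 1 array gave 1856 to 3352 genes in MYC-ER cells, 143 to 1800 in V394D cells, 27 to 340 for the difference, 0 to 1201 for ethanol and 29 to 35 list calls (33). Counts moved by over 1.5 times in MYC-ER cells without MYC-ER EtOH replicate 2 (1856). In V394D cells they did so without MYC-ER EtOH replicates 2 (534) and 3 (509), V394D EtOH replicates 1 (325), 2 (176) and 3 (143) and V394D 4-OHT replicates 1 (1800) and 2 (496). For the difference they did so without MYC-ER EtOH replicates 1 (48), 2 (75) and 3 (60), MYC-ER 4-OHT replicates 1 (49) and 2 (75), V394D EtOH replicates 1 (39), 2 (27) and 3 (70) and V394D 4-OHT replicate 1 (340). Ethanol calls were 0 without any 1 array, except 720 and 1201 without V394D 4-OHT replicates 1 and 2. Where an array left out leaves a pair, the fit still pools the spread over groups.

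The least-squares slope of rising genes (0.478) ran from 0.449 to 0.515 without 1 array, and was 0.510 with offset 16, 0.652 with median-centred processed signals, 0.679 with matrix values, 0.520 with all 12 arrays above background, 0.507 with slide as a fixed block, 0.554 with scaling, 0.501 over all tested genes and 0.367 on the left-out replicate. Its major-axis slope (0.636) ran from 0.590 to 0.782, and was 0.910 with median-centred processed signals, 1.21 with matrix values, 0.873 over all genes and 0.433 on the left-out replicate. For falling genes the least-squares slope (0.452) ran from 0.394 to 0.491, and was 0.532 without background correction, 0.368 with median-centred processed signals, 0.335 with matrix values, 0.658 with scaling and 0.215 on the left-out replicate. The major-axis slope (0.928) ran from 0.698 to 1.80, and was 1.91 with matrix values. Median centring called too few genes for a slope.

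List calls were 15 with median centring, 14 with scaling and 0 with an estimated correlation (lowest adjusted p 0.0641), and fry called 29. With median centring, test and median turned in V394D cells for glycolysis (0.59), adhesion (0.28), lysosome (0.29) and basal genes (0.0492), the median alone for SRF-MRTF (0.33) and SRF-TCF genes (0.13), and both for the differences of ribosome biogenesis (-0.70) and glycolysis (-0.63); slide as a fixed block turned the glycolysis difference (-0.0157). Scaling turned the test of the SRF-MRTF difference (median -0.10) and the adhesion difference (0.14), and the medians alone of lysosomal genes in V394D cells (0.19) and of the ribosome biogenesis difference (-0.13). Without the filter the luminal median in MYC-ER cells was 0.0045. None of these lists passed where its test or median turned. With median centring, V394D changes turned for AMOTL2 (0.28), CDC25B (0.21), CXCL1 (0.39), ITGB4 (0.23), KRT6B (0.0492), LAMB3 (0.0799), MT1E (0.62) and MYL6 (0.38). Scaling turned AMOTL2 (2.02), CXCL1 (0.93) and ZBED2 (0.0678) in V394D cells and the ITGB4 difference (2.33).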

Other observations

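The lists and their tests were chosen before the data were examined, and the example genes follow their p values in MYC-ER cells. Lists without a call by camera in any contrast still held genes that changed in MYC-ER cells. Among oestrogen receptor targets, the transcription factor MYB rose by 1.78 ± 0.11 and GREB1 by 1.08 ± 0.13 (1 of 3 ethanol arrays well above background), whereas the growth factor AREG changed by -0.91 ± 0.14, so that 4 of 14 members rose and 3 fell. Of p53 and apoptosis genes, 7 of 32 rose and 4 fell, with the BH3-only gene BBC3 at 1.101 ± 0.13, SESN1 at 0.85 ± 0.12 and SFN at -0.84 ± 0.17. In the ATF4 stress list 3 of 18 rose and 3 fell, with ATF3 at 1.08 ± 0.14 on 1 probe but -0.08 and -0.09 on others that did not pass, STC2 at 0.87 ± 0.16 and CEBPB at -0.35 ± 0.10. Metallothioneins in the heat shock and RNA-quality list fell, MT1E by 1.09, MT2A by 0.90 and MT1X by 0.88, though another MT1X probe gave 0.18 (adjusted p = 0.346), and 3 of 17 members rose while 3 fell. Of 18 TGF-beta targets 5 fell and 3 rose, including the repressor SNAI2 at -1.14 ± 0.12, PMEPA1 at -1.097 ± 0.13 and the receptor TGFBR2 at -1.09 ± 0.15. In the mesenchymal list 3 of 13 rose and 3 fell, with N-cadherin CDH2 at 1.00 ± 0.13 and the matrix enzyme LOXL2 at -1.07 ± 0.12.

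Of 25 translation factors and tRNA synthetases 4 rose, KARS1 by 0.64, EIF4EBP1 by 0.54 and EPRS1 by 0.49 among them. In the MYC network 3 of 17 rose and 2 fell, with MXI1 at 0.99 ± 0.13 and SKP2 at 0.65 ± 0.13. Among 28 interferon-response genes 2 rose and 2 fell, with IFIH1 at 0.42 ± 0.11, IFI27 at -0.65 ± 0.15 and ISG20 at -0.53 ± 0.13. Mitosis genes had 1 of 26 higher, KIF20A at 0.54 ± 0.13, and 1 lower, CDC25B at -0.55 ± 0.15, while UBE2C (-0.31 ± 0.11) did not pass. Of 22 markers of fibroblasts, endothelium and blood cells 4 were measured; CD68 fell in MYC-ER cells by 0.47 and in V394D cells by 0.50, and CD14 (0.31 ± 0.13) and DCN (0.22 ± 0.12) did not pass.

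Medians of these lists in MYC-ER and V394D cells, in that order, were 0.01 and -0.03 for oestrogen receptor targets, 0.04 and 0.11 for p53, -0.14 and -0.04 for ATF4, 0.10 and -0.02 for heat shock, -0.11 and -0.16 for TGF-beta, and -0.10 and -0.02 for mesenchymal genes. They were 0.09 and 0.11 for translation, 0.15 and 0.10 for the MYC network, -0.04 and -0.03 for interferon, -0.11 and 0.06 for mitosis and 0.13 and 0.05 for the other cell types. The lowest adjusted p among them was 0.0631, for TGF-beta targets in V394D cells, and the lowest in MYC-ER cells was 0.144, for translation factors. In MYC-ER cells fry did call oestrogen receptor targets upwards (adjusted p = 0.0129) and TGF-beta targets downwards (adjusted p = 0.0443). Median and mean differed in sign for heat shock genes in MYC-ER cells (0.10 and -0.03) and translation factors in V394D cells (0.11 and -0.03), and the mitosis test in V394D cells pointed down with a median of 0.06.

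Replicate arrays correlated across genes at 0.785 to 0.876 in MYC-ER ethanol, 0.659 to 0.797 in MYC-ER 4-OHT, 0.683 to 0.779 in V394D ethanol and 0.0847 to 0.351 in V394D 4-OHT samples. In the last group the lowest and highest values both involve replicate 3, the array with distorted values. Replicates 1 and 2 of that group correlated at 0.240. SNRNP70, KRT42P, KRT14 and SDC4 were called in the ethanol comparison as planned, but not with replaced backgrounds. For them V394D 4-OHT replicate 2 had log2 ratios of -1.98, -1.47, -1.32 and -1.63, whereas V394D 4-OHT replicate 1 had 0.33, 0.34, 0.41 and 0.19. Of 2782 genes with several kept probes, 6 had probes called in opposite directions in MYC-ER cells and no gene did in V394D cells.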
